A study of Mus musculus with 8 samples.

How the data were processed

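Poly(A) RNA was measured in 8 libraries from mouse hippocampus, 2 each of control tissue and of tissue at 12 h, 10 d and 6 wk after status epilepticus. Each library, made from polyadenylated RNA per the labels' protocols, pooled cDNA from 2 animals and was sequenced on a Genome Analyzer II, per the labels and the series' design text. How status epilepticus was induced, and the sex of the animals, are not given in the sources used here. Reads were mapped to mm9 with Bowtie at its default settings, and uniquely mapped reads were counted in RefSeq exons, per the series' design text. Those counts were not used here. For mRNA the authors deposited a fold and a q-value per transcript and time, each an average over pairwise comparisons per the file headers. How they computed the folds and q-values, and how libraries were scaled, is not given in the sources used here. When multiplied by 4, 100.0% of non-zero folds were whole millionths within 0.02, and when multiplied by 2, 53.5%, 47.9% and 48.8% were, as for means of 4 comparisons of 2 treated with 2 control libraries. A q-value from a pair of libraries compares those libraries and not the conditions. Genes listed at a fold of 0 by the authors share a single q-value per time, include the widely expressed Gapdh and Ppia, and were taken as having no fold (3475, 3031 and 4460 genes at 12 h, 10 d and 6 wk).

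The deposited table also held, per the file headers, counts of small RNA tags matching mature miRNAs in 8 columns, which the authors give without scaling. Columns were assigned to groups by the time in their names, and a library number only names a library. The labels describe poly(A) libraries only, so the preparation of the small RNA libraries, their mapping and their miRNA annotation are not given in the sources used here. Nothing says whether they came from the same pools, so their p-values measure only the spread between these libraries. A further 24 columns of values per sample were not used. The height of regions named for CREB within 2000 bases of a gene, a score the authors deposited on a scale that is not given, was used only for whether a gene had such a region.

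Of 29208 rows, 96 named no gene and were left out. The rest held 24921 RefSeq transcripts and 20258 gene symbols, 3285 of them on more than 1 row, and 97.8% of transcripts were found in the reference gene table. The first row in the table stood for a gene, since the planned choice of the row with most counts needed values per library. The plan had assumed values per library for mRNA. The rule used instead, a mean q under 0.05 with a mean fold of at least 1 in size, was set after the table had been seen. A mean of 4 signed folds can hide pairs that went opposite ways or had no fold, which is why smaller mean folds were counted as mixed. The rule does not set apart every such gene, since a mean of at least 1 in size can also come from pairs of opposite direction. For mRNA, tests between times and of any difference, values adjusted over the list alone and an estimated correlation between genes were not run. Nor were other scalings, filters and tools or left-out libraries. The mRNA values used here belong to no library.

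Before the data were examined, 27 gene lists, the rule for named genes and the alternatives for counts of changed genes were fixed, apart from those said elsewhere to have been chosen later. The lists covered immediate early genes, neuropeptides and growth factors, microglia and macrophages, reactive and resting astrocytes, oligodendrocytes, endothelium, pyramidal, granule and GABAergic neurons, neurogenesis and the cell cycle. They further covered GABA signalling, glutamate receptors, voltage-gated channels, cytokines, complement and antigen presentation, heat shock, cholesterol synthesis, extracellular matrix, synaptic vesicles, the respiratory chain, the clock, blood cells, choroid plexus, striatum and thalamus, and sex-linked genes. For 4 of the listed genes no row was found, and Myrf, Msmo1, Ciart and Drd1 were found under older symbols. Lists share members: C1qa, C1qb and C1qc, for example, stand in both the microglia and the complement lists. Genes were named if among the 6 largest rises or falls of a comparison, or if among the 2 called members of a list with the lowest mean q (3 where 5 or more were called). For differences between times the 3 largest either way were named, and 12 genes such as Fos, Gfap and Gad1 were named whatever their values. The conditions on counts and on single libraries in that rule could be applied to miRNAs only. The rule gave 174 mRNA names, and those printed were taken from these; some are not reported here.

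Lists were tested with cameraPR of limma 3.58.1 on ranks of the signed log2 of the mean fold, with a preset correlation of 0.01 and Benjamini-Hochberg adjustment over the lists of a time. In 100 simulated sets of folds modelled on 12 h, over 16783 genes, a list shifted by 1.5 on the log2 scale was called in 72%, and 3.6% of other lists had an unadjusted p under 0.05. The folds were shuffled over genes, which removes correlation between members of a list. These rates therefore need not hold for lists of correlated genes. Transcript lengths and GC content came from the longest protein-coding transcript of a gene in GENCODE vM1 on NCBIM37, the same assembly as mm9, and covered 97.2 to 97.3% of genes with a fold.

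Counts of miRNA tags, as deposited, were tested with edgeR 4.0.16 in R 4.3.3, using TMM factors, filterByExpr and the quasi-likelihood F-test on all 8 libraries in a fit of 4 groups, with Benjamini-Hochberg adjustment. The filter kept 422 of 1251 miRNAs, with 99.96% of tags, and the biological coefficient of variation was 15.5%. A miRNA with several genomic copies has the same tags at each, so its position is that of a listed copy. In counts simulated for 6 wk against control, with 200 of 422 miRNAs changed, 74% of 2-fold and 97% of 4-fold changes were recovered, and 7 unchanged miRNAs were called. Alternatives were DESeq2 1.42.0 size factors and tests, library size alone, limma-voom, other filters and thresholds, fits of the compared groups alone, and leaving out each library. With library size alone in place of TMM, the median log2 change against control moved by 0.14, 0.16 and 0.16 at 12 h, 10 d and 6 wk, so changes are relative to that shift. Python 3.11.15 with pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 did the remaining steps.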

Results

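Hippocampi of C57BL/6 mice were taken as control tissue or at 12 h, 10 d and 6 wk after status epilepticus, a prolonged seizure state. Each of the 4 groups had 2 libraries, and each library was a pool of cDNA from 2 animals, so the spread between libraries is a spread between pools. The comparisons ask how hippocampal RNA at each time differed from control. For mRNA, values came as the authors' own comparisons of each time with control, a mean signed fold and a mean q-value per gene, in which a fall is a negative fold. Gene positions are on mouse build mm9. A gene was counted as higher or lower where its mean q was under 0.05 and its mean fold was at least 1 in size. Genes passing mean q with a smaller mean fold were counted as mixed, since such a mean can come from pairs of opposite direction or pairs without a fold. Genes listed at a fold of 0 had a mean q of 0.635, 0.637 and 0.604 at 12 h, 10 d and 6 wk. If a pair without a fold has a q-value of that size, it would lift a mean of 4 above 0.05. Mixed genes would then be ones whose pairs went opposite ways. A mean fold of at least 1 in size does not exclude such pairs either, as 1 large fold can outweigh the others. Because no mRNA counts were used here, the depth behind each mRNA fold is unknown, and no error or n of its own stands beside it. A mean q of 1.21e-15 at 12 h, 8.66e-16 at 10 d and 9.82e-16 at 6 wk was shared by many of the named genes. Such values therefore do not rank those genes.

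For small RNA, tag counts per mature miRNA were used from 8 libraries, 2 per group. Totals ran from 545672 tags in SE 10 d library 4 to 3325374 tags in SE 12 h library 2, and 422 miRNAs entered the test. A count of 3 tags corresponded to between 0.902 and 5.5 CPM on library totals without TMM factors, a limit that covers counting error alone. All other CPM values were scaled with TMM factors. The most abundant miRNA in every library was miR-127-3p, with 16.5 to 20.5% of tags. Log2 CPM of the 2 libraries of a group correlated across miRNAs with r between 0.982 and 0.993, where miRNAs are not independent replicates.

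At 12 h, astrocyte filament genes and the growth factor gene Bdnf were among those that rose, and transcription factor genes of immature neurons were among those that fell. In the authors' deposited table, Gfap, the intermediate filament protein of astrocytes (NM_010277, chromosome 11, 102748650 to 102758514), had a mean fold of 2.83 (mean q 1.21e-15) and Vim, another intermediate filament protein, 4.17 (mean q 1.21e-15). Bdnf, a neurotrophin induced by neuronal activity (NM_007540, chromosome 2, 109514857 to 109567200), had a mean fold of 2.95 (mean q 0.00101) in the authors' deposited table. Neurod1, a transcription factor of differentiating granule neurons, had a mean fold of -8.78 (mean q 1.21e-15) in the authors' deposited table. From the authors' deposited table, 1704 genes rose, 1255 fell and 719 were mixed among 16783 genes with a fold.

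**Figure D1:**
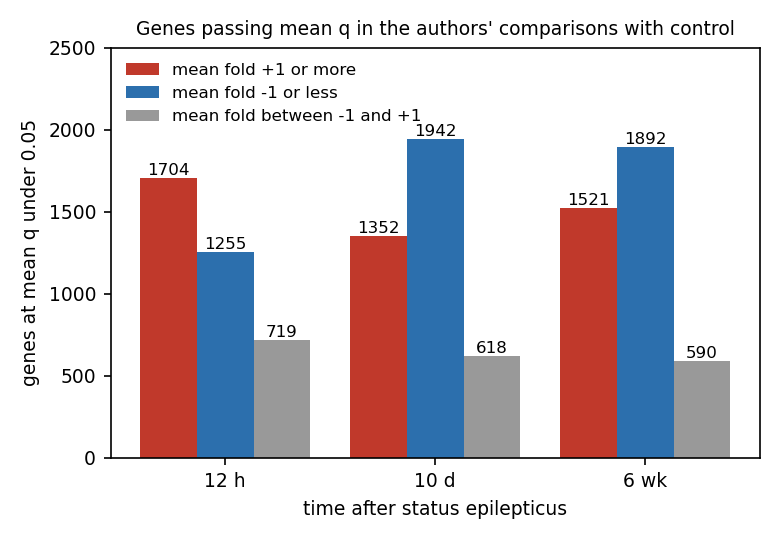
Genes with a mean q under 0.05 at each time after status epilepticus, counted from the authors' comparisons with control, with bars for a mean fold of at least +1, of -1 or below, and in between. The genes that rose numbered 1704, 1352 and 1521 at 12 h, 10 d and 6 wk, and those that fell 1255, 1942 and 1892.

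Of 20 measured genes of reactive astrocytes, 5 rose and 1 fell at 12 h. Serpina3n, a secreted protease inhibitor, had a mean fold of 1.42 and Cp, the copper-binding ferroxidase ceruloplasmin, 24.0 in the authors' deposited table. Of 24 neuropeptide and growth factor genes, 5 rose and 0 fell, among them Vgf, a secreted precursor peptide, and the neuropeptide Cck, at 2.99 and 20.4 in the authors' deposited table. Of 26 immediate early genes, 3 rose and 0 fell, including the AP-1 factor Fosl2 at 8.68 and the postsynaptic scaffold gene Homer1 at 14.5 in the authors' deposited table. Fos and Arc, named whatever their values, did not pass, at 11.7 (mean q 0.254) and 0.409 (mean q 0.247) in the authors' deposited table. Heat shock and unfolded protein genes gave 4 rises and 1 fall of 18, with the chaperone gene Hspa8 at 4.79 and the inducible Hspa1a at -23.0 in the authors' deposited table. Of 18 cytokine and chemokine genes, 1 rose and 1 fell, Ptgs2, the inducible cyclooxygenase, at 5.27 and Csf1, a growth factor for microglia, at -9.21 in the authors' deposited table. Microglia and macrophage genes gave 2 rises and 4 falls of 24, with the lysosomal gene Laptm5 at 3.47 and the homeostatic microglial gene Tmem119 at -3.34 in the authors' deposited table. The microglial marker Aif1 stood at 1.03 (mean q 0.759) in the authors' deposited table. Of 19 complement and antigen presentation genes, 2 rose and 0 fell, including complement C4b at 20.4 in the authors' deposited table.

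Neuronal lists went both ways at 12 h. At every time, counts of rises and falls in a list leave out its mixed members, which passed mean q. At 12 h these were 7 of the voltage-gated channel and 6 of the glutamate receptor genes, for example. Of 36 voltage-gated channel genes, 7 rose and 1 fell, with the potassium channel gene Kcnd3 at 2.19 and Kcnip3, a potassium channel interacting protein, at 3.37 in the authors' deposited table. GABA signalling genes gave 1 rise and 4 falls of 19, with Gabrd, the delta subunit of GABA-A receptors, at -135 (mean q 1.19e-05) in the authors' deposited table. Of 22 glutamate receptor genes, 3 rose and 4 fell, including Grin2c at 6.68 and Grm3 at -7.96 in the authors' deposited table. Interneuron markers gave 2 rises and 1 fall of 18, pyramidal neuron markers 4 and 3 of 15, and dentate granule markers 0 and 1 of 11. Neurogenesis genes gave 0 rises and 3 falls of 12, including Sox4, a transcription factor of immature neurons, at -5.79 in the authors' deposited table. Synaptic vesicle genes gave 3 rises and 3 falls of 18, and respiratory chain genes 5 and 6 of 22. For other cell types, 2 of 16 astrocyte genes rose and 1 fell, 2 of 18 oligodendrocyte genes rose and 4 fell, and 2 of 16 endothelial genes rose and 0 fell. Cell cycle genes gave 1 rise and 0 falls of 18, cholesterol synthesis genes 1 and 0 of 17, extracellular matrix genes 2 and 1 of 24, and clock genes 1 and 2 of 16. Blood cell genes gave 0 calls among 5 measured, and markers of striatum and thalamus 0 rises and 1 fall of 12. Of 12 choroid plexus genes, 3 rose and 0 fell, with the thyroid hormone carrier Ttr at 179 in the authors' deposited table. Of 4 Y-linked genes, 2 fell, Ddx3y to -65.8 and Eif2s3y to -65.9 in the authors' deposited table.

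No list passed limma's cameraPR at 12 h, where adjusted p ran from 0.112 for the choroid plexus and sex-linked lists to 0.901. Of the genes that changed, 532 (18.0%) had a mean fold of at least 20 in size, a scale that was not checked against counts here. The largest rises in the authors' deposited table included Nt5c3l at 240 and Smox, spermine oxidase, at 211, and the largest falls A430005L14Rik at -183 and Atxn7l2 at -178. Hes5, a target of Notch signalling, was also among them, at -142 in the authors' deposited table.

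At 10 d, genes of microglia, complement and reactive astrocytes were higher as groups, and genes of ion channels, glutamate receptors and granule neurons were lower. With a correlation between genes of 0.05 in place of 0.01, the latter 3 lists passed only narrowly (adjusted p 0.0414, 0.0499 and 0.0496 in cameraPR). So did cytokine genes, which were higher (adjusted p 0.0497). In the authors' deposited table, Cd68, a lysosomal protein of activated microglia and macrophages (NM_009853, chromosome 11, 69477873 to 69479564), had a mean fold of 488 (mean q 7.13e-08). Serping1, the complement C1 inhibitor, had a mean fold of 162 (mean q 4.59e-11) in the authors' deposited table. Prox1, the transcription factor that marks dentate granule cells, had a mean fold of -4.51 (mean q 1.22e-15), and the calcium buffer Calb1 -8.01 (mean q 9.19e-09) in the authors' deposited table. From the authors' deposited table, 1352 genes rose, 1942 fell and 618 were mixed among 17227 with a fold.

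Of 24 microglia and macrophage genes, 6 rose and 2 fell at 10 d, with a median log2 fold of 3.64 and an adjusted p of 6.74e-06 in cameraPR. Laptm5 had a mean fold of 14.0 and Csf1r, the receptor for microglial growth factors, 3.89 in the authors' deposited table. The homeostatic gene Tmem119 and the tetraspanin Cd53 went the other way, at -2.66 and -32.7 in the authors' deposited table. Of 20 complement and antigen presentation genes, 6 rose and 0 fell (median log2 fold 4.21, adjusted p 8.87e-05), among them C4b at 42.4 in the authors' deposited table. Reactive astrocyte genes passed with 2 rises and 0 falls of 19 (adjusted p 0.00149), with Vim at 7.96 and Serpina3n at 7.53 in the authors' deposited table. Gfap stood at 8.47 with a mean q of 0.194 in the authors' deposited table. Cytokine and chemokine genes passed with 3 rises and 0 falls of 23 (adjusted p 0.00676), including Tgfb1 at 49.9 and the interleukin 6 co-receptor Il6st at 2.24 in the authors' deposited table. Of 16 genes of resting astrocytes, 6 rose and 0 fell without the list passing (adjusted p 0.431), with the water channel Aqp4 at 4.10 and Sox9 at 8.24 in the authors' deposited table.

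Of 36 voltage-gated channel genes, 15 fell and 3 rose at 10 d (median log2 fold -1.58, adjusted p 0.00155). The potassium channel gene Kcnc2 had a mean fold of -22.7, Kcnd3 -7.40 and the calcium channel gene Cacna1e -5.91 in the authors' deposited table. Glutamate receptor genes gave 5 falls and 0 rises of 22 (adjusted p 0.00767), with the NMDA receptor subunit Grin2b at -4.08 and the AMPA receptor subunit Gria1 at -1.44 in the authors' deposited table. Dentate granule markers gave 6 falls and 0 rises of 11 (adjusted p 0.0116), including the cation channel gene Trpc6 at -58.5 in the authors' deposited table. Interneuron markers gave 5 falls and 1 rise of 18 (adjusted p 0.034, or adjusted p 0.108 with a correlation between genes of 0.05 in place of 0.01), with Gad2, a GABA synthesising enzyme, at -4.23 and the neuropeptide Npy at -3.74 in the authors' deposited table. GABA signalling genes gave 6 falls and 3 rises of 19 (adjusted p 0.0354, or adjusted p 0.108 with a correlation of 0.05 and 0.0887 ranked among genes of like length), with the receptor subunit Gabra4 at -10.5 in the authors' deposited table. Cholesterol synthesis genes gave 3 falls and 2 rises of 17 (adjusted p 0.0359, or adjusted p 0.108 with a correlation of 0.05 and 0.0665 ranked among genes of like length), including Srebf2, the regulator of the pathway, at -20.8 in the authors' deposited table. Among changed genes, split by transcript length into 5 classes of equal size, the share that rose at 10 d was 54.8% in the class with the shortest and 30.2% in the class with the longest transcripts.

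Blood cell genes passed with 0 calls among 5 measured (median log2 fold 4.11, adjusted p 0.0403, or adjusted p 0.0785 with a correlation of 0.05). That call was also lost on signed mean q (0.204), ranked among genes of like length (0.079) or GC content (0.0518), and with length medians taken out (0.0542). It was kept only with GC medians taken out (0.0442). Choroid plexus genes passed with 1 rise and 0 falls of 12 (adjusted p 0.00676), Ttr at 558 in the authors' deposited table. The sex-linked list passed with 1 fall of 4 (adjusted p 0.0112, or adjusted p 0.0559 on signed mean q), Ddx3y at -30.8 in the authors' deposited table. Lists that did not pass at 10 d had adjusted p of 0.0767 or more. Among them, pyramidal neuron markers gave 6 falls and 1 rise of 15 (adjusted p 0.171), with the glutamate transporter Slc17a7 at -1.92 and the mineralocorticoid receptor Nr3c2 at -11.2 in the authors' deposited table. Synaptic vesicle genes gave 7 falls and 0 rises of 18 (adjusted p 0.0767, or adjusted p 0.00301 on signed mean q), with Syp at -2.68 and Syn2 at -15.5 in the authors' deposited table. Extracellular matrix genes gave 6 rises and 1 fall of 24, with Sparc at 3.16 in the authors' deposited table. Immediate early genes gave 4 and 1 of 26, with Fosb at 30.2 and Fos at 9.37 (mean q 0.0449, near the threshold) in the authors' deposited table. Neuropeptide genes gave 2 rises and 4 falls of 23, oligodendrocyte genes 4 and 3 of 18, endothelial genes 3 and 0 of 16, and neurogenesis genes 3 and 4 of 13. Cell cycle genes gave 2 rises and 0 falls of 18, heat shock genes 4 and 4 of 18, respiratory chain genes 6 and 4 of 22, clock genes 2 and 4 of 16, and striatal and thalamic markers 2 and 1 of 12.

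Of the genes that changed, 719 (21.8%) had a mean fold of at least 20 in size. The largest rises in the authors' deposited table also held Pdlim2 at 367 and Lbp, which binds bacterial lipopolysaccharide, at 234 (mean q 0.0307). The largest falls there held Cyp4v3 at -278 and Klf16 at -222.

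**Figure D2:**
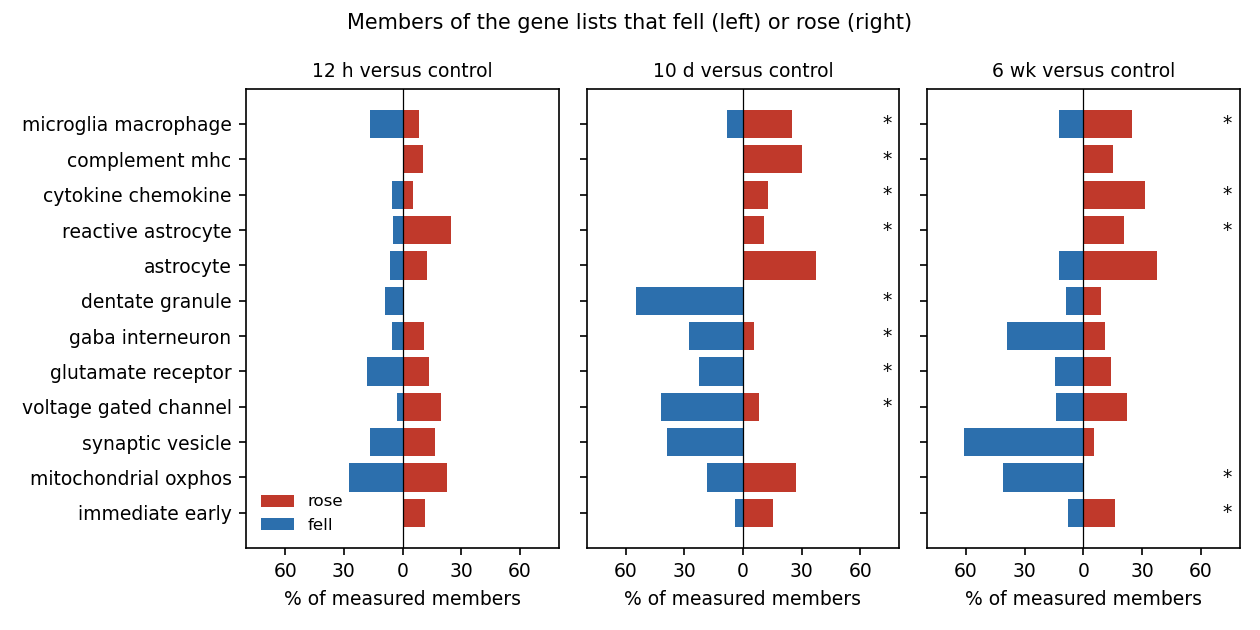
Percent of the measured members of 12 gene lists that fell (bars to the left) or rose (bars to the right) at each time, counted from the authors' comparisons with control; an asterisk marks an adjusted p under 0.05 before rounding in cameraPR. Mixed members are not drawn. Voltage-gated channel genes gave 15 falls of 36 at 10 d, and respiratory chain genes 9 falls of 22 at 6 wk.

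At 6 wk, genes of reactive astrocytes and cytokine signalling were higher as groups. Microglial genes were also higher as a group and genes of the mitochondrial respiratory chain lower, but both calls were lost with a correlation between genes of 0.05 (adjusted p 0.129 and 0.0617 in cameraPR). In the authors' deposited table, Gfap had a mean fold of 10.5 (mean q 9.82e-16) and Serpina3n 17.1 (mean q 3.50e-11). Bdnf had a mean fold of 10.9 (mean q 9.82e-16), and the interneuron peptides Sst and Npy had -81.9 (mean q 4.50e-11) and -7.95 (mean q 1.79e-09) in the authors' deposited table. Gad1, the main GABA synthesising enzyme (NM_008077, chromosome 2, 70400221 to 70440069), had a mean fold of -2.82 (mean q 5.78e-07) in the authors' deposited table. From the authors' deposited table, 1521 genes rose, 1892 fell and 590 were mixed among 15798 with a fold.

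Of 19 reactive astrocyte genes, 4 rose and 0 fell at 6 wk, with a median log2 fold of 4.10 and an adjusted p of 2.68e-05 in cameraPR. Cytokine and chemokine genes gave 6 rises and 0 falls of 19 (adjusted p 0.00102), including Tnfrsf1a, a receptor for tumour necrosis factor, at 76.2 and Il6st at 7.16 in the authors' deposited table. Microglia and macrophage genes gave 6 rises and 3 falls of 24 (adjusted p 0.0143, or adjusted p 0.129 with a correlation of 0.05), with the fractalkine receptor Cx3cr1 at 7.04 and Csf1r at 2.66 in the authors' deposited table. Cd68 stood at 113 with a mean q of 0.304 in the authors' deposited table. Complement and antigen presentation genes did not pass (adjusted p 0.0519, and 0.0213 to 0.22 over the alternatives, passing when ranked among genes of like length, at 0.0213, or GC content, at 0.0326), with 3 rises and 0 falls of 20, among them C4b at 63.1 in the authors' deposited table. Immediate early genes passed before rounding (adjusted p 0.05), a call lost with a correlation of 0.05 (adjusted p 0.22) and on signed mean q (adjusted p 0.123), with 4 rises and 2 falls of 25, Fosl2 at 7.99 and the phosphatase gene Dusp6 at -3.50 in the authors' deposited table. Of 22 respiratory chain genes, 9 fell and 0 rose (median log2 fold -1.72, adjusted p 0.00432, or adjusted p 0.0617 with a correlation of 0.05), with the complex II subunit Sdha at -2.21 and the complex III subunits Uqcrc1 and Uqcrc2 at -2.43 and -2.40 in the authors' deposited table. Among changed genes at 6 wk, the share that rose was 25.9% in the class with the shortest transcripts and 68.6% in the class with the longest.

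The remaining lists did not pass at 6 wk. Synaptic vesicle genes gave 11 falls and 1 rise of 18 (adjusted p 0.434, or adjusted p 0.00669 on signed mean q), with synaptophysin, Syp, at -9.50 and synapsin, Syn1, at -1.66 in the authors' deposited table. Interneuron markers gave 7 falls and 2 rises of 18 (adjusted p 0.185 in cameraPR). Cck among them stood at -132 (mean q 0.0443, near the threshold) in the authors' deposited table. GABA signalling genes gave 6 falls and 4 rises of 19, including Slc12a5, the chloride extruder of neurons, at -4.23 and the transporter Slc6a11 at -12.1 in the authors' deposited table. Pyramidal neuron markers gave 4 falls and 2 rises of 15, with Slc17a7 at -2.65, and dentate granule markers 1 and 1 of 11, with C1ql2 at -153 in the authors' deposited table. Neurogenesis genes gave 4 rises and 1 fall of 12, with Sox11 at 3.69 and Neurod1 at -49.8 in the authors' deposited table. Resting astrocyte genes gave 6 rises and 2 falls of 16, with Aqp4 at 5.62 in the authors' deposited table, and oligodendrocyte genes gave 3 rises and 4 falls of 18. Clock genes gave 3 rises and 6 falls of 16, including Clock at 12.6 and the output gene Dbp at -16.8 in the authors' deposited table. Voltage-gated channel genes gave 8 rises and 5 falls of 36, glutamate receptor genes 3 and 3 of 21, neuropeptide genes 4 and 3 of 24, and heat shock genes 2 and 4 of 18. Endothelial genes gave 4 rises and 1 fall of 16, cell cycle genes 2 and 1 of 18, extracellular matrix genes 1 and 2 of 24, and cholesterol synthesis genes 0 and 2 of 17. Blood cell and choroid plexus genes gave 0 calls among 6 and 10 measured, and striatal and thalamic markers 0 rises and 2 falls of 11. Of 4 Y-linked genes, 2 rose, Ddx3y at 4.59 and Eif2s3y at 3.92 in the authors' deposited table.

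Of the genes that changed, 885 (25.9%) had a mean fold of at least 20 in size. The largest rises in the authors' deposited table included Pggt1b at 269 and Gpnmb, a glycoprotein of phagocytes, at 179, and the largest falls the scaffold gene Begain at -316 and the potassium channel interacting protein gene Kcnip2 at -269.

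**Figure D3:**
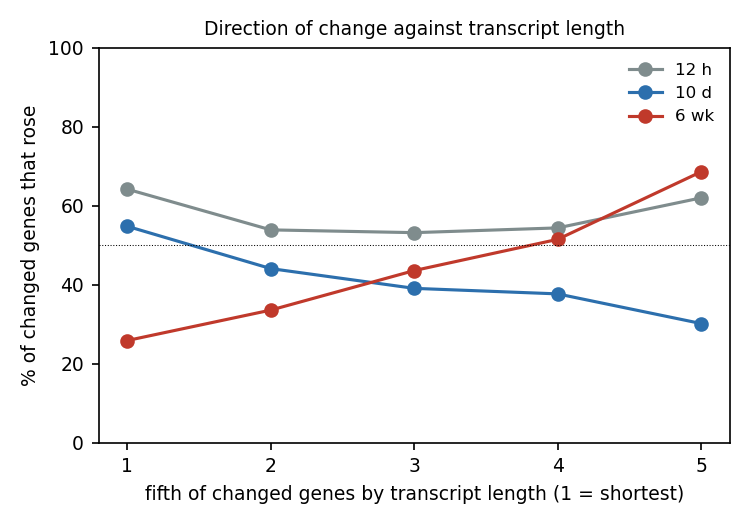
Share of changed genes that rose (percent, vertical axis) in 5 equal classes of the changed genes ordered by transcript length (horizontal axis), with a line for each time after status epilepticus. The share went from 25.9% in the shortest class to 68.6% in the longest at 6 wk, and from 54.8% to 30.2% at 10 d.

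Calls recurred between times. Genes that fell at both 10 d and 6 wk numbered 739, against 235.5 for independent lists, and genes that rose at both numbered 316, against 131.2. Opposite calls at 10 d and 6 wk were made for 132 and 110 genes, against 163.4 and 189.0. For 12 h and 10 d, 572 genes fell at both (149.8 for independent lists) and 413 rose at both (141.4), and for 12 h and 6 wk, 553 fell (153.0) and 433 rose (165.2). At all 3 times, 294 genes fell and 141 rose, Dbp, Syp and Grm3 among the former and Vim, Serpina3n, C4b and Hspa8 among the latter. Because every time was set against the same control libraries, part of these overlaps may come from those libraries. The size of that part was not simulated, since no mRNA counts were used here.

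In small RNA at 12 h, 2 miRNAs were called by edgeR, miR-145a-3p higher and miR-690 lower. The mature sequence of miR-145a-3p (chromosome 18, 61807481 to 61807502, minus strand, in no other gene) gave 28.2 and 37.2 CPM in control and 89.2 and 71.3 at 12 h, a log2 change of 1.26 (SE 0.214, adjusted p 0.0365, edgeR). The other arm of its hairpin, miR-145a-5p, named here after its values were seen, was at 112 and 119 CPM in control and 85.1 and 88.0 at 12 h, a log2 change of -0.42 (adjusted p 0.212, edgeR). The tags of miR-690 (chromosome 16, 28600026 to 28600047) gave 356 and 491 in control and 172 and 158 at 12 h, a log2 change of -1.36 (SE 0.231, adjusted p 0.0365, edgeR). Of 422 miRNAs, 84 had an unadjusted p under 0.05, and the count of 2 was 13 with library size alone (12 rises and 1 fall), 13 with DESeq2 (9 and 4), 25 with no filter (23 and 2) and 0 to 4 with a library left out. Both calls were lost without control library 8, SE 12 h library 1, SE 12 h library 2 or SE 10 d library 3, and that of miR-145a-3p also without control library 7 or SE 6 wk library 5.

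At 10 d, 4 miRNAs rose and 0 fell in edgeR, with 85 at an unadjusted p under 0.05. These were miR-21a-5p and miR-146a-5p, which are induced in inflammation and gliosis, miR-142-5p of blood-derived cells, and miR-10a-5p of the Hoxb locus. The CPM values of miR-21a-5p (chromosome 11, 86397622 to 86397643, minus strand, in an exon of Vmp1) were 621 and 806 in control and 2480 and 2900 at 10 d, a log2 change of 1.91 (SE 0.158, adjusted p 0.000156, edgeR). For miR-146a-5p (chromosome 11, 43187937 to 43187958, minus strand, in no other gene) they were 2340 and 3030 in control and 8790 and 10100 at 10 d, a log2 change of 1.82 (SE 0.163, adjusted p 0.000156, edgeR). The log2 change of miR-142-5p (chromosome 11, 87570369 to 87570389, in an intron of A430104N18Rik) was 1.51 (SE 0.145, adjusted p 0.000194, edgeR). That of miR-10a-5p (chromosome 11, 96178500 to 96178522, in an exon of Hoxb4) was 1.57 (SE 0.263, adjusted p 0.0164, edgeR), and the call was lost without control library 7 or SE 10 d library 4. The count of 4 was 7 with DESeq2 and 18 with library size alone, with 0 falls in each, 29 with no filter (24 rises and 5 falls), 8 without SE 10 d library 3 and 7 without SE 12 h library 1, SE 12 h library 2 or SE 6 wk library 6.

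At 6 wk, 27 miRNAs rose and 17 fell, with 116 at an unadjusted p under 0.05 in edgeR. The log2 changes of miR-146a-5p, miR-142-5p, miR-10a-5p and miR-21a-5p were 2.10, 1.88, 2.24 and 1.40, with SE of 0.164, 0.145, 0.266 and 0.156. The inflammatory miRNA miR-155-5p (chromosome 16, 84714388 to 84714410, in an exon of its lincRNA host) was at 0.971 and 3.98 CPM in control, from 1 and 6 tags, and 35.7 and 38.0 at 6 wk, a log2 change of 3.71 (SE 0.479, adjusted p 0.00111, edgeR) that lay between 3.17 without control library 7 and 5.15 without control library 8. The CPM of miR-211-5p (chromosome 7, 71350717 to 71350738, in an intron of Trpm1) went from 5.83 and 5.97 to 63.0 and 129, a log2 change of 4.01 (SE 0.549, adjusted p 0.00142, edgeR) that lay between 3.42 and 4.35 over the alternatives. For miR-212-5p (chromosome 11, 74986905 to 74986927, in an intron of 1700016P03Rik), whose precursor is induced by neuronal activity, the log2 change was 1.28 (SE 0.142, adjusted p 0.000555, edgeR). Among falls, miR-3059-5p (chromosome 10, 101235338 to 101235359, in an intron of Mgat4c) had a log2 change of -1.35, and miR-148a-5p, miR-488-5p, miR-184-3p, miR-7b-5p and miR-3078-5p lay between -1.17 and -0.96. The calls of the last 4 were lost in some fits that left out a library, and that of miR-3078-5p also with library size alone, DESeq2 and limma-voom. The count of 44 was 20 without SE 6 wk library 5 and 63 with library size alone (53 rises and 10 falls).

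**Figure D4:**
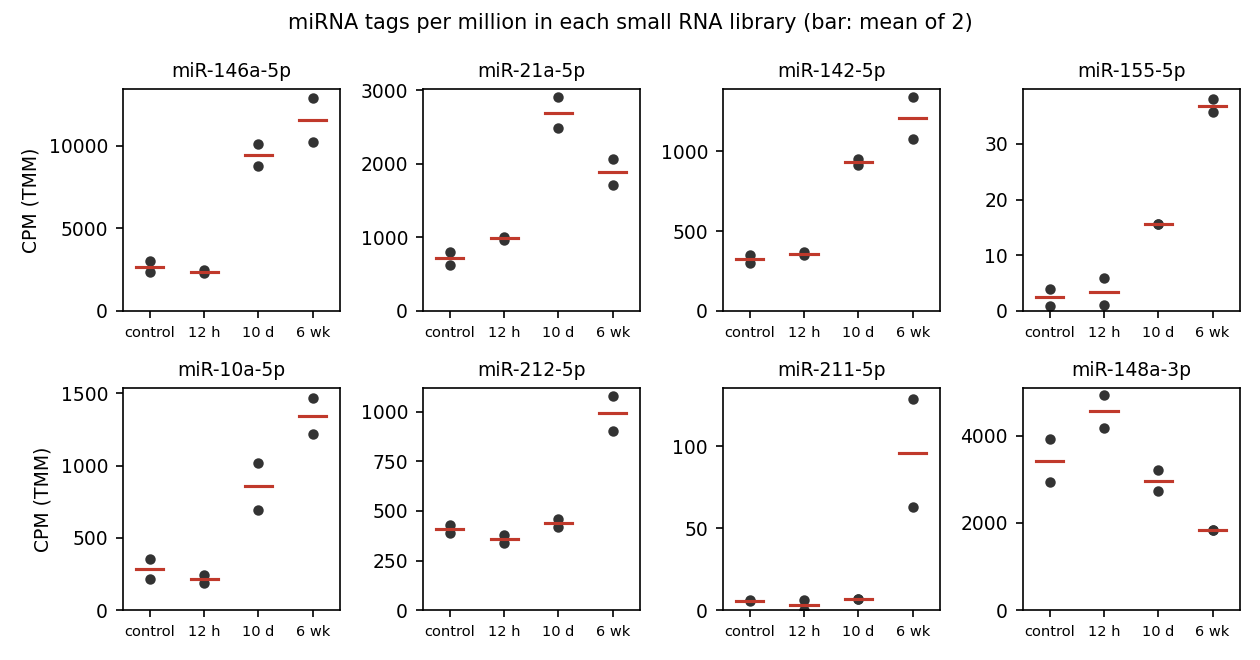
CPM with TMM scaling (vertical axes) of 8 miRNAs in each small RNA library of control and of 12 h, 10 d and 6 wk after status epilepticus; each point is a library and each bar the mean of 2. Those of miR-146a-5p were 2340 and 3030 in control and 10200 and 12900 at 6 wk, and those of miR-211-5p 63.0 and 129 at 6 wk.

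Between times, 12 miRNAs differed between 10 d and 12 h (11 higher at 10 d), 7 between 6 wk and 10 d (6 higher at 6 wk) and 92 between 6 wk and 12 h (55 higher at 6 wk). A test of any difference among the 4 groups called 65. Numbers at an unadjusted p under 0.05 were 88, 74, 140 and 148 in edgeR. With a library left out, these counts of 12, 7, 92 and 65 ran from 4 to 17, 0 to 9, 30 to 97 and 26 to 68, and were lowest without SE 12 h library 1, SE 10 d library 3, SE 12 h library 2 and SE 6 wk library 5. The 12 were also 6 and 7 without SE 12 h library 2 and SE 10 d library 4, and the 7 were 4 without SE 12 h library 2 and 3 without SE 12 h library 1, SE 10 d library 4 or either 6 wk library. Without SE 12 h library 1 and SE 6 wk libraries 5 and 6, the 92 were 47, 46 and 47, and without SE 12 h libraries 1 and 2 and SE 6 wk library 6 the 65 were 32, 31 and 34. DESeq2 and no filter gave 21 and 26 for 10 d against 12 h, and 23 and 39 for 6 wk against 10 d, for which library size alone gave 3 (3 and 0), and no filter gave 111 for any difference. Against control, the 4 miRNAs that rose at 10 d all rose at 6 wk, where independent lists give 0.256. Simulated unchanged groups against the same control libraries gave 0.08 shared calls, both directions together. With no miRNA changed, that simulation cannot show how many shared calls the control libraries add to lists of 4 and 27. Log2 changes at those times correlated across miRNAs with r = 0.60, against 0.51 in the simulation, and their covariance was 0.232 against 0.056. For 12 h and 10 d, no call was shared, r was 0.57 against 0.51 and the covariance 0.136 against 0.056, and for 12 h and 6 wk, no call was shared, r was 0.28 against 0.52 and the covariance 0.09 against 0.055. A split would leave each time a single control library and was not made, so part of the excess over independent lists may come from these libraries.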

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

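The tests of transcript length, neuron share, Y-linked genes and choroid plexus were chosen only after the results they bear on had been seen, and so were the limit of 0.1 on the correlation left by the length ranking and the version of the neuron share test without small folds, which was added after the first version's result. The neuron share test was first meant for synaptic vesicle genes at 6 wk and was moved to channel genes at 10 d because the former list did not pass.

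The changes after status epilepticus of several miRNAs differed between times by a test of the difference itself, edgeR's quasi-likelihood test. Between 10 d and 12 h the log2 difference was 2.00 for miR-146a-5p (adjusted p 0.000138), 1.97 for miR-10a-5p (adjusted p 0.00286), 1.65 for miR-455-3p (adjusted p 0.0392) and -0.92 for miR-153-3p (adjusted p 0.0274). Between 6 wk and 10 d it was 3.77 for miR-211-5p (adjusted p 0.00849), 1.18 for miR-212-5p (adjusted p 0.00433), 1.13 for miR-431-5p (adjusted p 0.00849) and -0.84 for miR-3059-5p (adjusted p 0.0434). Between 6 wk and 12 h it was 4.38 for miR-211-5p, 2.96 for miR-155-5p and 2.64 for miR-10a-5p, and -1.31 for miR-148a-3p, -1.42 for miR-3059-5p and -1.45 for miR-6240, with adjusted p between 0.000207 and 0.0221. SE 12 h library 1 held 0 tags of miR-211-5p and 1 of miR-155-5p, and without SE 12 h library 2 the fitted values were 10.1, which is no bound because the remaining 12 h library is at 0, and 5.06, against lowest values of 3.74 and 2.57 over the alternatives. Over the alternatives run for 10 d against 12 h, miR-146a-5p and miR-10a-5p passed in 15 of 15, miR-153-3p in 11 of 15 and miR-455-3p in 7 of 14. For 6 wk against 10 d, miR-212-5p passed in 14 of 15, miR-211-5p in 13 of 14, miR-431-5p in 12 of 15 and miR-3059-5p in 5 of 15, and for 6 wk against 12 h all passed in 15 of 15 except miR-6240, in 11 of 15. All 4 calls for 6 wk against 10 d were lost without SE 10 d library 3.

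Voltage-gated channel genes were lower at 10 d, when long transcripts rose less often than short ones, and respiratory chain genes were lower at 6 wk, when short transcripts rose less often, a call lost with a correlation between genes of 0.05 (adjusted p 0.0617). Ranked among genes of like length, the channel list kept its direction with an adjusted p of 0.00933 (0.00155 before), while the correlation of fold with length went from -0.11 to 0.00 over measured genes, as ranking within bins makes it by construction, and from -0.10, already at the limit, to -0.06 among changed genes, and the kept call argues against length as the whole cause. The respiratory chain list passed at 0.0213 (0.00432 before), with a correlation that went from 0.14 to 0.00 over measured genes, again by construction, but only from 0.29 to 0.19 among changed genes, so length and a change in these transcripts cannot be told apart there. Fewer neurons alone would raise the markers of every other cell type alike. Yet the 10 d medians of the microglia list, 3.64 [95% bootstrap interval 2.25, 5.66], and the oligodendrocyte list, 0.00 [-0.32, 0.74], lay 3.64 apart on the log2 scale. They stayed apart without mean folds under 1 in size, which otherwise count as 0 (oligodendrocyte 0.46 [-1.16, 1.47]). This argues against fewer neurons as the only change. The microglia list was already known to be higher, which separates the medians whatever the share of neurons. The test therefore cannot tell whether fewer neurons lowered the channel genes. The bootstrap resampled the genes of a list and not libraries. The interval of resting astrocyte markers, 0.00 [0.00, 1.32], overlapped that of microglia without such folds, at 1.78 [1.16, 3.04], and that of endothelial markers, 0.30 [-0.76, 2.86], did so in both versions. Fewer neurons beside a gain of microglia stay open for the channel genes, as granule, pyramidal and synaptic vesicle lists gave 6, 6 and 7 falls against 0, 1 and 0 rises and reactive astrocyte genes were higher, and so does a lower level of channel transcripts after status epilepticus as a hypothesis.

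Ddx3y and Eif2s3y were lower at 12 h and higher at 6 wk, which pools that differ in the sex of their animals might give. At 10 d Ddx3y was also called lower, at -30.8, Eif2s3y stood at -32.2 without a call in the authors' deposited table, and the sex-linked list passed downward (median log2 fold -4.28). Called lower at 12 h were 2 of the 4 Y-linked genes measured, and none of the 4 was called higher then. The sex-linked list had a median log2 fold of -5.06 at 12 h (adjusted p 0.112 in cameraPR). The other 2 were not called, which does not show that they were unchanged. Of the 5 sex-linked genes listed, 4 had a fold at each time, and Xist, the listed gene that is not Y-linked, was called at none. Since the sex of the animals is not given in the sources used here, the sex of the pools and a change in these genes cannot be told apart. If the pools did differ in sex, that difference could enter every comparison with control. No biological explanation was tested.

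Ttr, which the choroid plexus makes in large amounts, was higher at 12 h and 10 d, and choroid plexus left on the tissue is a candidate explanation. The other 11 choroid plexus genes measured had a median log2 fold of 2.47 at 10 d, at the 99.5 percentile of 10000 random lists of their size, as that explanation needs. The full list of 12 had already passed upward at 10 d (adjusted p 0.00676 in cameraPR). The rank of these 11 therefore largely repeats that result and is no added support. The random lists were drawn from all genes with a fold, whatever their level. None of these 11 was called at 10 d, and no member of the list is in another list. A change in Ttr within hippocampus stays open and was not tested.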

How the results depend on the processing

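For gene lists, all alternatives were chosen after the data had been seen; so were mean q under 0.01, the median over rows and leaving out extreme folds for mRNA. The counts of mRNA genes that changed stayed within 1.5 times under each alternative run, from 2146 to 3929 at 12 h, 2454 to 4363 at 10 d and 2528 to 4515 at 6 wk. Of named genes, Cry2 at 6 wk turned from -3.18 to 4.1 with the median over its rows; the cause was not tested. The list count at 6 wk was 2 in place of 5 with a correlation between genes of 0.05, which widens the variance of a list. Length was first corrected by taking out the median fold of 20 length bins. That was replaced, after its results were seen, by ranking within bins, because the medians lay near 0. The first version gave 10 lists at 10 d and 6 at 6 wk, with adjusted p of 0.00359 for channels and 0.00406 for the respiratory chain, and the ranking gave 10 and 6, with 0.00933 and 0.0213. For GC content the medians gave 13 and 5 and the ranks 12 and 7. The GC ranks made synaptic vesicle genes at 10 d (adjusted p 0.044 in cameraPR) and extracellular matrix genes at 6 wk (0.0471, against 0.0753 as reported) pass. They ended the calls of GABA signalling (0.065) and blood cell genes (0.0518) at 10 d. The synaptic vesicle list at 6 wk, first meant for the length and neuron share tests, was dropped from them because it did not pass (adjusted p 0.434; 0.00669 on signed mean q). Signed mean q also ended the calls of GABA signalling (adjusted p 0.0501), cholesterol (0.123), blood cell (0.204) and sex-linked genes (0.0559) at 10 d and of immediate early genes at 6 wk (0.123), and made synaptic vesicle genes at 10 d pass (0.00301). Complement genes at 6 wk, at 0.0519 as reported, passed in both length versions (0.0213 ranked, 0.0442 with medians) and ranked for GC content (0.0326), but not with GC medians (0.0547), on signed mean q (0.15) or with a correlation of 0.05 (0.22).

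For miRNAs, 12 h against control gave 13 calls with library size alone, 13 with DESeq2, 25 with no filter, 4 with the compared groups alone and 8 at adjusted p under 0.1, against 2 as reported. For 10 d, in the same order without the compared groups, the counts were 18, 7, 29 and 19, against 4. At 6 wk they were 74 at adjusted p under 0.1 and 18 with a log2 change of at least 1, against 44. For 10 d against 12 h, DESeq2 gave 21, no filter 26, adjusted p under 0.1 gave 25 and a log2 change of at least 1 gave 7, against 12. For 6 wk against 10 d, DESeq2 gave 23, no filter 39 and adjusted p under 0.1 gave 25, and DESeq2 size factors, library size, a mean of 20 counts, the compared groups alone and a log2 change of at least 1 gave 3 each, against 7. For 6 wk against 12 h, a log2 change of at least 1 gave 29, against 92. For any difference, no filter gave 111 and adjusted p under 0.1 gave 120, against 65. The cause was not tested, apart from thresholds, which act by construction.

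With a library left out, a group of 1 was assumed to vary like the others. Counts then ran from 0 to 4 at 12 h, 3 to 8 at 10 d, 20 to 52 at 6 wk, 4 to 17 for 10 d against 12 h, 0 to 9 for 6 wk against 10 d, 30 to 97 for 6 wk against 12 h and 26 to 68 for any difference. At 12 h the count was 0 without SE 12 h library 1, SE 12 h library 2 or SE 10 d library 3, 1 without either control library and 4 without SE 6 wk library 6. At 10 d it was 8 without SE 10 d library 3 and 7 without SE 12 h library 1, SE 12 h library 2 or SE 6 wk library 6, and at 6 wk 20 without SE 6 wk library 5. For 10 d against 12 h it was 4, 6 and 7 without SE 12 h library 1, SE 12 h library 2 and SE 10 d library 4. For 6 wk against 10 d it was 0 without SE 10 d library 3, 4 without SE 12 h library 2 and 3 without any other library of the treated groups. Without SE 12 h library 1, SE 12 h library 2, SE 6 wk library 5 and SE 6 wk library 6 in turn, 6 wk against 12 h gave 47, 30, 46 and 47, and any difference 32, 31, 26 and 34. Of results for named miRNAs under an alternative, 675 kept direction and call and 72 lost the call; for named genes these numbers were 314 and 48. Of the 314 for named genes, 268 came from mean q under 0.01, which leaves the fold as it was by construction. With the median over the rows of a gene, which can change the fold, 46 kept direction and call, 9 lost the call and 1 was reversed. No paired analysis was possible because the small RNA columns carry no replicate letter and the mRNA values belong to no library. For mRNA and its gene lists, other scalings, filters and tools, fits of the compared groups alone, the replicate block, left-out libraries and an estimated correlation were not run because the mRNA values belong to no library. Those mRNA values are the authors' mean folds and mean q-values used here, so these limits hold for them alone. Whether the further 24 columns of values per sample, which were not used, would allow such runs was not tested. Pseudocounts and filters for normalized values were not run because no such values were used. The miRNAs whose names stand on several rows held the same counts on each.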

Other observations

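The groups of miRNAs and their tests were chosen only after their values had been seen. The immune and glial group holds miR-21a-5p, miR-146a-5p, miR-142-5p and miR-155-5p, which were already called above. The p-values of these groups therefore describe the same values again and are no independent support. The tests on CREB regions and seed matches were fixed before their values were seen.

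Of 6 miRNAs of immune cells and reactive glia, 3 rose and 0 fell at 10 d (median log2 change 1.66; camera, adjusted p 4.67e-17, or adjusted p 0.023 with an estimated correlation), and 4 rose at 6 wk (median 1.64, adjusted p 7.76e-14, or adjusted p 0.0324 with an estimated correlation). Of 5 miRNAs whose precursors respond to neuronal activity, 4 rose and 0 fell at 6 wk (median 0.99, camera adjusted p 1.18e-06), a call lost with an estimated correlation (adjusted p 0.0805). Of 10 miRNAs abundant in neurons, 3 fell and 0 rose at 6 wk (median -0.43, camera adjusted p 0.000204), again lost with an estimated correlation (adjusted p 0.0866). Of 4 miRNAs of choroid plexus and ciliated cells, 1 rose at 6 wk, miR-211-5p (camera adjusted p 0.037, or adjusted p 0.269 with an estimated correlation). The activity group at 10 d and the neuron group at 12 h, with 0 members called, passed only with the preset correlation (camera adjusted p 0.022 and 0.0252, or adjusted p 0.393 and 0.55 with an estimated correlation). The remaining tests of these 4 groups gave adjusted p of 0.161 or more. Groups for oligodendrocytes and red blood cells had too few measured members for a test.

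The transcription factor CREB is activated by neuronal activity, and genes with a region named for it might rise more often than they fall. The odds ratio of having such a region, for genes that rose against genes that fell, was 1.00 [95% interval 0.86, 1.17] at 12 h and 1.04 [0.90, 1.20] at 10 d, where Fisher's exact test gave p of 1 and 0.61 and neither direction was shown. At 6 wk it was 0.83 [0.72, 0.95], with p = 0.00866 in Fisher's exact test before adjustment over the 3 times. There, 35.6% of genes that rose and 40.0% of genes that fell had a region, against 36.3% of genes not called, a direction opposite to the hypothesis. The test took no account of transcript length or GC content, with which direction also went at 6 wk. Of changed genes, 57.8% rose in the class of 5 with the lowest GC content and 29.1% in that with the highest. Whether GC content or length accounts for the odds ratio was not tested. What the regions were called from is not given in the sources used here.

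The miRNAs higher at 6 wk could lower their target transcripts. Genes with a match to bases 2 to 8 of a miRNA in the 3 prime UTR were compared by fold rank at 6 wk with genes without a match, within 20 bins of UTR length, in 10000 permutations over 14794 genes. The difference in mean rank percentile was 1.08 for miR-21a-5p, -0.05 for miR-146a-5p, 0.50 for miR-155-5p, 1.08 for miR-142-5p and 0.11 for miR-132-3p, with adjusted permutation p between 0.472 and 0.945. No shift was shown in either direction, and with folds averaged over pairs the test has unknown power. The measure was changed from medians to ranks before the test was run.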
